A study of Oryza sativa with 12 samples.

How the data were processed

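RNA sequencing counts per gene were examined in 12 libraries of developing rice (Oryza sativa) seed, 3 from each of the 4 tissues pericarp, aleurone, embryo and endosperm. Per the labels' protocols, plants were grown in the field without treatment, RNA was isolated with the PicoPure kit and libraries were made with the NEBNext Ultra kit from 10 ng of total RNA per sample for the HiSeq2500. The design text calls the 3 libraries of a tissue biological replicates. It does not say whether the tissues came from the same seeds. The cultivar, the seed stage, the aligner, the genome build and the use of strand are not given in the sources used here.

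The deposited table held 37878 genes with total read counts per library, which were whole numbers and had not been normalized, per the file headers. It also held RPKM, TPM and CPM columns, per the file headers, and these 36 columns were not used. Columns were assigned to tissues by letters in the column header. Al and Em are the starts of aleurone and embryo, Pc was read as letters of pericarp, which no other tissue name holds, and Se was assigned to the endosperm because the other 3 names were taken. Libraries are named by the number in their header (pericarp 1, 3 and 4, aleurone 1, 2 and 3, embryo 2, 3 and 4, endosperm 2, 3 and 4), which is not the number in the sample titles. The headers name 2 sequencing lanes. Aleurone 1, aleurone 2, embryo 2, pericarp 1 and endosperm 2 carried lane 6, and the other libraries lane 5.

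Gene names and coordinates came from the deposited table, in which 412 genes had a symbol and 24 a description. The reference table of locus tags matched 0 of the table's identifiers. Genes without a symbol entered every count of genes and are otherwise left unnamed, apart from 3 identifiers.

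Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count of 10), which left 16347 genes, 286 of them with a symbol. TMM factors scaled the libraries, and a single quasi-likelihood fit (glmQLFit and glmQLFTest) held all 12 libraries with tissue as the only term. The common dispersion was 3.49, a biological coefficient of variation of 1.87, and the prior degrees of freedom were 4.64. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 and a fold of at least 2 over the genes tested. The F test between any tissues used the adjusted p alone. Standard errors of log2 fold changes are the absolute log2 fold change over the square root of F. A gene was enriched or depleted in a tissue when it was called the same way against each of the other 3. The contrast of a tissue with the rest is its log coefficient minus the mean of the other 3. A gene absent from 1 of those 3 can therefore be called although another tissue holds more of it. The contrast was planned for the gene lists, and its counts of called genes were added after the data were seen.

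Levels are CPM, counts scaled to a common library size, after TMM scaling, as mean ± SD over 3 libraries. Where all libraries of a tissue were at 0, a fold is given as at least the ratio to a floor of 3 counts over the tissue's 3 libraries. Floors cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. They do not cover the loss of transcripts from a library, so such a fold is no bound on the level in the tissue itself. Library totals ran from 2879282 to 24412371. The floor depends on the totals and the TMM factors. It was 0.137 CPM in pericarp, 0.122 in endosperm, 0.104 in aleurone and 0.0497 in embryo. Genes counted per library were compared with exact two-sided permutation tests.

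Lists of genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, which gave 68 tests adjusted together, and again with an estimated correlation. Before the data were examined, 10 lists with 100 members had been fixed. Of these members 85 were not matched by symbol or identifier, 10 were used and 5 were dropped. An unmatched member can be in the table under another symbol, as GBSSI is as WAXY, GAMYB as GAM1 and GIF1 as CIN2, and these entered the later lists alone. GT2 lay on another chromosome than its planned member, the description of OSH15 did not match, and SHR1, IPK1 and ANS1 matched by symbol alone without being marked as sure. Of 24 planned keyword lists 2 had a match, GT2 and SUT1, and they were too small to test. A further 29 lists with 241 genes were drawn up from the table's symbols after the names were seen and before any test across genes. The lists of DREB1 genes and of lamina inclination genes had no tested member and gave no result.

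By the rule fixed before the data were examined, the genes named are tissue-enriched genes with a described product and at least 50 CPM, the largest called changes in 3 of the pairwise comparisons under the same conditions, the 3 most abundant members of each list, and called members that went against their list's median. Because few genes carry a symbol, other called genes with a symbol are also named, and these were chosen after their values were seen: UBP26, APX1, ASA1, HSP81-1, CYCB2-1, SPL12, MCM6, MCM7, NEK2, WOX4, H2B.9, HOX7, HOX20, RAB16D, RPL11_2, TROL, LTD, AOC, TIFY6A, IAA13, ARF10, MYBS2 and CSLC10. So were LTP2-A_1, SWEET4, SWEET15 and SUT4 among list members and the 3 identifiers without a symbol. Genes with near-identical copies (the ATG8, histone H2B, RPL11, LTP110-A and LTP2-A families) may share reads, and their values are uncertain.

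On simulated counts for aleurone against endosperm over 16346 genes, the quasi-likelihood test recovered 1 of 67 genes changed 8-fold, 9 of 67 changed 60-fold and 25 of 66 changed 500-fold, and called 1 unchanged gene. DESeq2 1.42.0 (local trend) recovered 12, 24 and 30, and called 510 unchanged genes. Limma voom recovered 1, 1 and 12, and called 23 unchanged genes. The counts were drawn once, from each gene's mean over all libraries and the dispersions of the edgeR fit. They held no other difference between tissues and no loss of transcripts particular to a library. They therefore cannot show which method's calls in the real data are right.

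The alternatives were DESeq2, DESeq2 size factors or library totals in the edgeR fit, other filters and fold minimums, the replicate number as a block, fits of 2 tissues alone, and each library left out. Further alternatives were added after seeing the data: lane as a covariate, limma voom, other quasi-likelihood settings, TMM without the most abundant genes, thinning to the smallest total, and leaving out the shallowest aleurone and endosperm libraries. Alternatives and shares that need storage protein genes were not run, because GT2, by its description a glutelin, was the only such gene matched in the table. Figures were drawn with matplotlib 3.10.9.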

Results

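Transcripts of 4 tissues of developing rice seed were counted: the pericarp, the maternal fruit wall; the aleurone, the outer cell layer of the endosperm; the embryo; and the starchy endosperm. Each tissue had 3 libraries. Total counts per library ran from 2879282 to 6301388 in pericarp, from 5689112 to 16005961 in aleurone, from 14205388 to 18169845 in embryo and from 6367350 to 24412371 in endosperm. The design asks in which tissue each gene is active, and the 6 pairs of tissues are its comparisons. Coordinates are those of the deposited table, whose genome build is not given in the sources used here.

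Embryo libraries held the most genes and pericarp libraries the fewest. A mean of 15974 ± 1428 genes had a count in embryo, 11144 ± 2787 in aleurone, 9106 ± 2026 in endosperm and 5326 ± 662 in pericarp (SD, n = 3 libraries each). The 10 most abundant genes took 48.3% ± 5.44 of the counts in endosperm, 31.8% ± 9.57 in aleurone, 20.9% ± 9.06 in pericarp and 6.29% ± 1.17 in embryo (SD, n = 3). Exact two-sided permutation tests of the number of genes gave p = 0.1 for 5 of the 6 pairs and p = 0.4 for aleurone against endosperm, with adjusted values of 0.12 and 0.4. A p of 0.1 is the smallest that 3 libraries against 3 allow.

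Few pericarp genes were seen in all 3 libraries. Of 9880 genes with a count in any pericarp library, 1718 (17.4%) had one in all 3, against 6310 of 15970 (39.5%) in aleurone, 5021 of 13392 (37.5%) in endosperm and 12829 of 19074 (67.3%) in embryo. Spearman correlations across genes, which are not independent replicates, were 0.316 to 0.366 between pericarp libraries, 0.523 to 0.676 in aleurone, 0.587 to 0.726 in endosperm and 0.824 to 0.889 in embryo. Each pericarp library correlated more with aleurone 3 than with any other pericarp library, at 0.466, 0.432 and 0.392 for pericarp 1, 3 and 4. Aleurone 1 correlated more with embryo 2 (0.613) than with aleurone 2 (0.523). Of 3361 genes counted in all 9 libraries of the other tissues, each pericarp library lacked 30.6% to 43.2%, and 318 had no count in any of the 3. Aleurone 2 and endosperm 3 also lacked many genes, with 3071 and 2285 at 0 there and at 50 counts or more in both other libraries of the tissue.

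**Figure D1:**
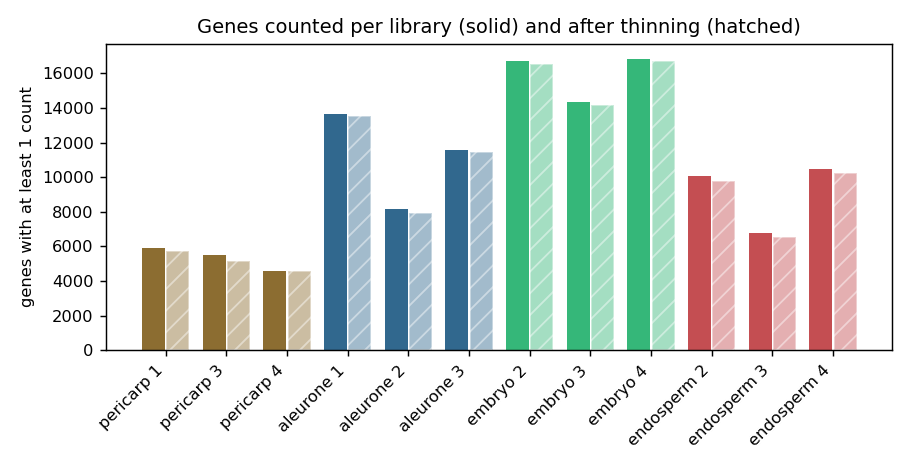
Number of genes with at least 1 count (vertical axis) in each of the 12 libraries (horizontal axis), as counted (solid bars) and after thinning every library to 2879282 counts (hatched bars). The 3 pericarp libraries stay lowest after thinning, at 4599 to 5711 genes, and the lowest library of another tissue holds 6567.

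Between aleurone and endosperm, which share an origin in the fertilised central cell, the starch gene WAXY and the oil body gene OLE18 stood far apart in level. WAXY, the granule-bound starch synthase that makes amylose (chromosome 6, 1931535 to 1935014), had 58540 ± 31170 CPM in endosperm and 2101 ± 874 in aleurone (SD, n = 3). OLE18, an oleosin of the oil body surface (chromosome 3, 32134440 to 32134958), had 2447 ± 495 CPM in aleurone and 187 ± 173 in endosperm. LEA19, a late embryogenesis abundant gene, had 1925 ± 1690 CPM in aleurone and 103 ± 79.0 in endosperm. None of the 3 passed the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, at log2 fold changes of -4.80 ± 1.10 (SE, adjusted p = 0.196), 3.71 ± 0.68 (adjusted p = 0.0896) and 4.23 ± 1.06 (adjusted p = 0.241).

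The test called 7 genes higher in aleurone than in endosperm and 0 lower, none with a symbol, while 3198 genes had an unadjusted p below 0.05. DESeq2 called 2359 genes, limma voom 719 and a fit of these 6 libraries alone 82, and scaling by DESeq2 size factors gave 10 higher and 2 lower. Without single libraries the count was 4 (aleurone 1), 3 (aleurone 3, and embryo 2, 3 or 4), 66 (pericarp 1), 20 (pericarp 4), 0 (endosperm 3) and 2 (endosperm 4).

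Between embryo and endosperm, WAXY had the lowest adjusted p among named genes, at 58540 ± 31170 CPM in endosperm and 7.96 ± 10.4 CPM in embryo (SD, n = 3). It fell by 12.84 ± 1.53 on the log2 scale (SE, edgeR quasi-likelihood with Benjamini-Hochberg adjustment, adjusted p = 0.000955). OLE18 was higher in embryo, at 1816 ± 503 CPM, with a log2 fold change of 3.28 ± 0.66 (adjusted p = 0.0452, edgeR). SAPK2, a protein kinase of abscisic acid and stress signalling, had 83.4 ± 16.2 CPM in embryo and 0 in every endosperm library, at least 683-fold higher (adjusted p = 0.0482, edgeR). The alcohol dehydrogenase gene ADH1 had 326 ± 84.8 CPM in embryo and 51.8 ± 15.4 in endosperm, and the pyruvate decarboxylase gene PDC2 805 ± 130 and 112 ± 99.99. Neither fermentation gene passed (adjusted p = 0.121 for both, edgeR).

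In all, 20 genes were higher in embryo and 92 lower than in endosperm, against 61 and 71 with library totals alone and 4266 called in a fit of these 6 libraries. Without single libraries the 112 calls became 69 (aleurone 3), 55, 49 and 51 (embryo 2, 3 and 4), 253, 213 and 221 (pericarp 1, 3 and 4), and 71 and 67 (endosperm 3 and 4). The WAXY call ended with limma voom (adjusted p = 0.955). The OLE18 call ended without any of 8 libraries (aleurone 1, 2 and 3, embryo 2, 3 and 4, endosperm 3 and 4; edgeR adjusted p 0.0574 to 0.161), and the SAPK2 call without any of the 9 aleurone, embryo and endosperm libraries (0.0685 to 0.216).

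Between pericarp and endosperm, WAXY was again the endosperm gene, at 1212 ± 1010 CPM in pericarp (SD, n = 3), and fell by 5.59 ± 1.15 on the log2 scale (SE, adjusted p = 0.0253, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). OLE18 was higher in pericarp, at 1504 ± 223 CPM, with a log2 fold change of 3.01 ± 0.65 (adjusted p = 0.032, edgeR). The autophagy genes ATG8B and ATG8C, whose products coat the autophagosome, had 274 ± 161 and 114 ± 51.8 CPM in endosperm and 0 in all pericarp libraries. By the counting floor they were at least 2010-fold and 833-fold lower in pericarp (adjusted p = 0.00919 and 0.00965, edgeR). The floor does not cover lost transcripts, and each pericarp library lacked 30.6% to 43.2% of the genes counted in all 9 other libraries. ATG8A, of the same family, had 90.2 ± 37.6 CPM in pericarp and 73.4 ± 16.3 in endosperm. PHR2, a regulator of the phosphate starvation response, was at 81.4 ± 16.6 CPM in endosperm and 0 in pericarp, at least 596-fold lower (adjusted p = 0.0157, edgeR). The other called genes with a symbol were RPL11_2, CDKG-1, CESA5 and PXG, all lower in pericarp.

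Of 402 calls 38 were higher and 364 lower in pericarp, against 46 and 82 with library totals alone, and a fit of these 6 libraries called 0 genes, where DESeq2 called 4932 and limma voom 1688 over all libraries and edgeR had 4959 at an unadjusted p below 0.05. With lane as a covariate edgeR called 182. Without single libraries the count was 254, 658 and 129 (aleurone 1, 2 and 3), 129, 172 and 143 (embryo 2, 3 and 4), 1015 and 616 (pericarp 1 and 3), and 153, 615 and 113 (endosperm 2, 3 and 4). The WAXY call ended without aleurone 3, pericarp 3 or 4, or endosperm 2 or 4 (edgeR adjusted p 0.0535 to 0.0641), the OLE18 call without aleurone 1 or 3, any embryo library, or endosperm 3 or 4 (0.0504 to 0.0822), and the PHR2 call without endosperm 4 (0.0522). Calls of CDKG-1, CESA5 and PXG ended without 6, 8 and 8 of the libraries, and those of ATG8B, ATG8C and RPL11_2 held whichever of the 12 was left out.

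Between aleurone and pericarp, the sugar transporter genes SUT1 and SWEET11, the lipid transfer gene LTP and OLE18 were abundant in both tissues. SUT1, a sucrose transporter (chromosome 3, 4249429 to 4255303), had 669 ± 405 CPM in aleurone and 246 ± 76.2 in pericarp (SD, n = 3). SWEET11, a sugar efflux carrier (chromosome 8, 28419731 to 28421978), had 353 ± 146 and 438 ± 247. LTP (chromosome 12, 916286 to 916774) had 797 ± 263 and 551 ± 114. None of the 4 passed the test, at log2 fold changes of 1.44 ± 1.40, -0.31 ± 1.45, 0.53 ± 0.95 and 0.70 ± 0.61 (SE, adjusted p from 0.568 to 1, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). CDKG-1, a cyclin-dependent kinase gene, had 77.9 ± 58.6 CPM in aleurone and 0 in pericarp, at least 570-fold above the counting floor (adjusted p = 0.0248, edgeR).

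ATG8B, ATG8C, PHR2 and RPL11_2, at 0 in pericarp, were also called higher in aleurone, at least 205-fold, 339-fold, 255-fold and 324-fold above the counting floor (adjusted p = 0.0185 to 0.0246, edgeR). In all 265 genes were higher in aleurone and 1 lower. The count was 0 in a fit of these 6 libraries, with lane as a covariate, with library totals alone, and without any of aleurone 1 and 3, embryo 2, 3 and 4, and endosperm 2 and 4, where the calls of these 5 genes ended (adjusted p up to 0.0871). It was 435 without aleurone 2, 860 and 498 without pericarp 1 and 3, and 663 without endosperm 3, and over all libraries 5091 genes had an unadjusted p below 0.05, DESeq2 called 4436 and limma voom 1681.

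Between aleurone and embryo, the symbol-bearing genes called were SUT1, SWEET11 and WAXY, all higher in aleurone. SUT1 and SWEET11 had no count in any embryo library and were at least 13500-fold and 7100-fold higher in aleurone (adjusted p = 0.0183 and 0.03, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). WAXY was higher in aleurone by 8.04 ± 1.28 on the log2 scale (SE, adjusted p = 0.0125, edgeR). LTP had 797 ± 263 CPM in aleurone and 22.3 ± 21.7 in embryo (SD, n = 3) and did not pass (adjusted p = 0.0898, edgeR). OLE18 and the dehydrin gene RAB16C, at 217 ± 195 and 252 ± 132 CPM in aleurone and embryo, differed by less than their errors, with log2 fold changes of 0.43 ± 0.61 and -0.22 ± 1.95 (SE).

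Of 73 calls 70 were higher in aleurone and 3 lower, and a fit of these 6 libraries called 388. The count was 39 and 42 without aleurone 2 and 3, and 35, 36 and 33 without embryo 2, 3 and 4. The WAXY call ended without aleurone 2 or embryo 2 (edgeR adjusted p = 0.0563 and 0.0758) and with limma voom (adjusted p = 0.979). The SUT1 call ended without any aleurone or embryo library (0.0501 to 0.142) and the SWEET11 call without any of these or pericarp 3 (0.0519 to 0.185).

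Between embryo and pericarp, SUT1 and SWEET11 were at least 4950-fold and 8820-fold lower in embryo (adjusted p = 0.0124 and 0.014, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). LTP fell by 4.63 ± 1.10 on the log2 scale (SE, adjusted p = 0.044, edgeR) and WAXY by 7.25 ± 1.24 (adjusted p = 0.011). Higher in embryo were ATG8B, ATG8C, RPL11_2, PHR2, CDKG-1 and the ubiquitin protease gene UBP26, all at 0 in pericarp, and SAPK2, CESA5 and the ascorbate peroxidase gene APX1, each with a count in 1 pericarp library. RPL11_2, a ribosomal protein gene, had 96.5 ± 20.5 CPM in embryo (SD, n = 3), at least 707-fold above the counting floor in pericarp (adjusted p = 0.011, edgeR). APX1 had 211 ± 63.0 CPM in embryo and 0.0401 ± 0.0695 in pericarp (adjusted p = 0.0309, edgeR).

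In all, 357 genes were higher and 99 lower in embryo, against 194 and 92 with library totals alone, and a fit of these 6 libraries called 5638. With lane as a covariate edgeR called 186. Without single libraries the 456 calls became 248, 694 and 175 (aleurone 1, 2 and 3), 122, 129 and 108 (embryo 2, 3 and 4), 925 (pericarp 1), and 830 and 241 (endosperm 3 and 4). The SUT1 call ended without embryo 3 or 4 (edgeR adjusted p = 0.0606 and 0.0539), the SWEET11 call without any embryo library (0.054 to 0.0648), the WAXY call without embryo 2 (0.0505) and the LTP call without any of 10 libraries, all but pericarp 1 and endosperm 3 (0.0507 to 0.143). The calls of CDKG-1 and PHR2 ended without aleurone 3 or any embryo library, and those of SAPK2, APX1, UBP26 and CESA5 without 6, 6, 10 and 10 libraries. Those of ATG8B, ATG8C and RPL11_2 held whichever of the 12 was left out.

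**Figure D2:**
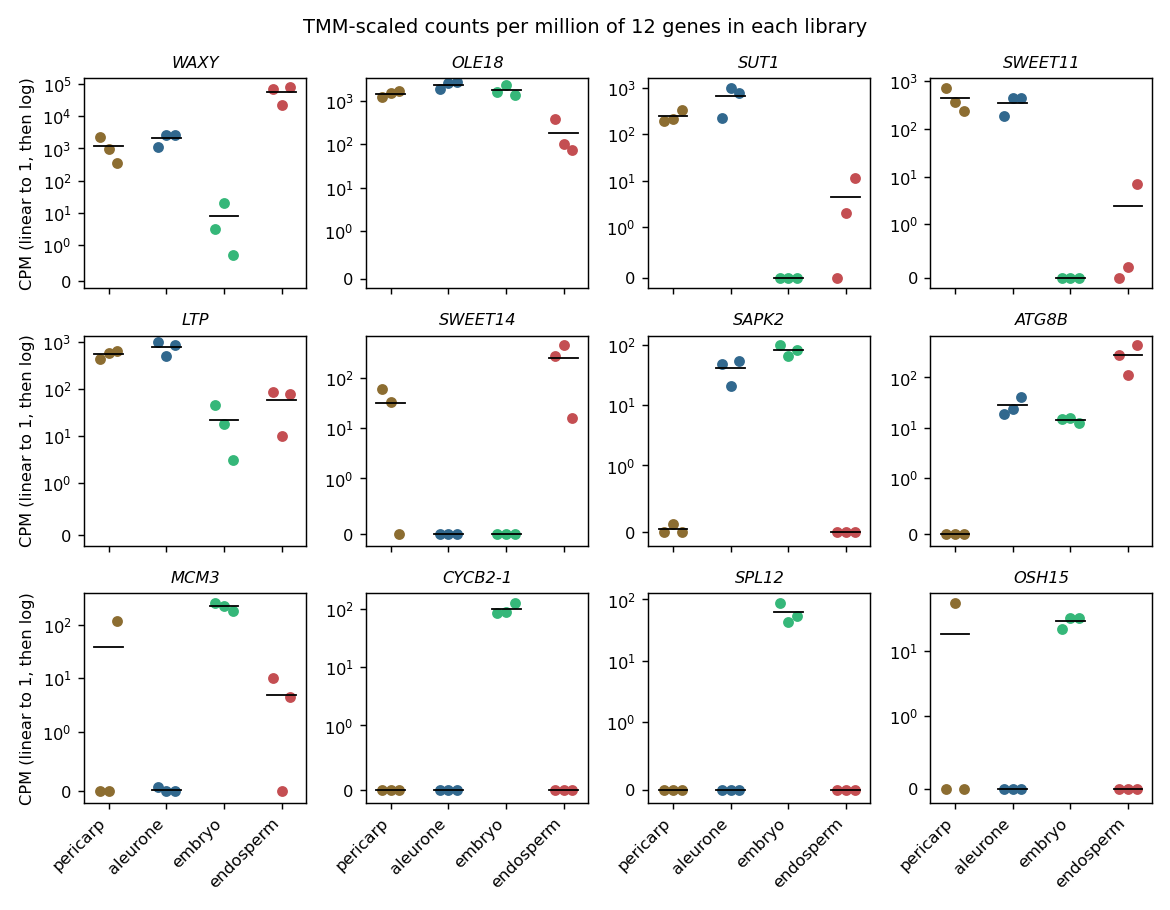
CPM after TMM scaling (vertical axis, linear up to 1 and logarithmic above) of 12 genes in the 4 tissues (horizontal axis), with a dot per library and a black line at the mean of 3 libraries. WAXY is highest in endosperm at 58540 CPM, SUT1 and SWEET11 are at 0 in all embryo libraries, and CYCB2-1 and SPL12 have counts in the embryo libraries alone.

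Set against the other 3 tissues, 5 of 13 genes of DNA replication and the cell cycle were called higher in embryo. So were 2720 of all 16347 genes tested. CYCB2-1, a B-type cyclin of mitosis (chromosome 4, 27014231 to 27016653), had 101 ± 23.6 CPM in embryo (SD, n = 3) and 0 in the 9 other libraries, at least 738-fold to 972-fold higher. MCM3, a subunit of the replicative helicase, had 222 ± 38.7 CPM in embryo, 39.1 ± 67.6 in pericarp, 4.89 ± 5.14 in endosperm and 0.0247 ± 0.0427 in aleurone. The 5 were CYCB2-1, MCM3, MCM6, MCM7 and NEK2 (adjusted p from 0.0141 to 0.0404, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and 8 did not pass, among them FEN1a and RBR1. As a list they did not pass camera (adjusted p = 0.287, and 0.725 with an estimated correlation). Of 10 histone H2B genes H2B.2 and H2B.9 were called higher, at 191 ± 26.5 and 83.6 ± 43.7 CPM (adjusted p = 0.0416 and 0.0304, edgeR), and the list did not pass (camera adjusted p = 0.716). Pericarp held a mean of 72.4 CPM of H2B.2, and 27.8 of MCM7 against 50.6 in embryo. CYCB2-1, MCM3, MCM6, MCM7, NEK2, H2B.2 and H2B.9 were called against the mean of the rest and in no pair of tissues.

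Of 5 tested KNOX and WOX homeobox genes, regulators of meristems, OSH15, OSH71 and WOX4 were higher in embryo against the rest, at 28.4 ± 5.69, 35.3 ± 16.1 and 5.74 ± 0.81 CPM (SD, n = 3; adjusted p = 0.048, 0.0284 and 0.0141, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). OSH15 also had a mean of 18.3 CPM in pericarp, and 0 in aleurone and endosperm. OSH71 had 16.3 in aleurone, and 0 in endosperm and pericarp. WOX5 was lower in embryo against the rest (adjusted p = 0.0479, edgeR). Like OSH15, OSH71 and WOX4, WOX5 was called in no pair of tissues. It was at 0 in embryo, at least 1560-fold below endosperm (77.7 ± 19.9 CPM), 717-fold below pericarp (35.6 ± 31.2) and 76.2-fold below aleurone (3.78 ± 6.55). The list did not pass (camera adjusted p = 0.786). SPL12, a squamosa promoter-binding factor gene, had 61.7 ± 23.8 CPM in embryo and 0 elsewhere. HSP81-1, a heat shock protein 90 gene present in every library, had 2381 ± 530 CPM in embryo and a log2 fold change of 1.65 ± 0.43 (SE, adjusted p = 0.024, edgeR). HOX7 and HOX20, of the HD-Zip family, were called higher in embryo against the mean of the rest, although aleurone held more of both, 28.6 ± 5.92 against 6.37 ± 5.50 CPM and 41.5 ± 15.1 against 19.4 ± 7.78. SUT1, SWEET11, WAXY, LTP, WOX5 and DAO, an auxin oxidase gene at 2.65 ± 2.80 CPM, were the symbol-bearing genes called lower. SPL12, HSP81-1, HOX7, HOX20 and DAO were also called in no pair of tissues.

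For embryo against the rest 2720 genes were higher and 183 lower, 61 of them with a symbol, and the count was 1833 and 78 without aleurone 2 and 3, 1429 and 992 without embryo 2 and 4, and 317, 1170 and 120 without endosperm 2, 3 and 4. With the replicate block it was 392 and with lane as a covariate 1863. Without aleurone 3 edgeR lost 60 of the 61 symbol-bearing calls, those of CYCB2-1, SUT1, SWEET11 and APX1 at adjusted p = 0.0532, and WAXY alone stayed. From 9 (pericarp 3) to 54 (endosperm 4) of the 61 were lost without any other library.

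Set against the rest, the endosperm was marked by WAXY, with a log2 fold change of 7.75 ± 0.77 (SE, adjusted p = 0.000211, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and by lower OLE18, which fell by 3.34 ± 0.62 (adjusted p = 0.014). ATG8B was higher (adjusted p = 0.00144, edgeR), at 274 ± 161 CPM in endosperm, 28.0 ± 11.9 in aleurone, 14.5 ± 1.91 in embryo and 0 in pericarp. Of 4 autophagy genes ATG8B and ATG8C were called higher and 2 did not pass. SWEET14, a sugar efflux carrier, had 242 ± 213 CPM in endosperm, 31.1 ± 30.0 in pericarp and 0 in aleurone and embryo (SD, n = 3; adjusted p = 0.0205, edgeR). ASA1, an anthranilate synthase gene of tryptophan synthesis, had 932 ± 253 CPM in endosperm and 138 ± 104 in aleurone, the next highest tissue (adjusted p = 0.0477, edgeR). The cellulose synthase gene CESA5 and the caleosin gene PXG were also higher, at 251 ± 145 and 201 ± 150 CPM (adjusted p = 0.0454 and 0.0197, edgeR). PXG thereby moved against OLE18 in the list of oil body, late embryogenesis and dehydrin genes.

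For endosperm against the rest 388 genes were higher and 38 lower, against 99 and 45 with library totals alone. The count was 134, 252 and 119 without aleurone 1, 2 and 3, 163, 150 and 162 without embryo 2, 3 and 4, 984 without pericarp 1, and 134, 237 and 112 without endosperm 2, 3 and 4. The calls of WAXY and ATG8B stayed without any single library, the OLE18 call ended without endosperm 3 or 4 (edgeR adjusted p = 0.0584 and 0.0601), the SWEET14 call without any of the 9 aleurone, embryo and endosperm libraries (0.0509 to 0.0782), and those of ASA1, CESA5, PXG and ATG8C without 10, 10, 7 and 7 libraries.

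Set against the rest, pericarp and aleurone shared SUT1 and SWEET11. SUT1 was called higher in pericarp and in aleurone (adjusted p = 0.0174 and 0.0135, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and so was SWEET11 (adjusted p = 0.0119 and 0.0293, edgeR). Both genes were at 0 in embryo, and in endosperm they had 4.36 ± 5.96 and 2.37 ± 3.94 CPM (SD, n = 3). SAPK2 was the other symbol-bearing gene called in aleurone (adjusted p = 0.0403, edgeR), at 41.1 ± 17.5 CPM, although embryo held 83.4 ± 16.2 and the gene was called higher there too. In pericarp ATG8B, ATG8C, RPL11_2, PHR2, CDKG-1, UBP26 and CESA5 were called lower.

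For pericarp against the rest 57 genes were higher and 334 lower, against 95 and 156 with library totals alone, and the count was 193, 606 and 104 without aleurone 1, 2 and 3, 95, 157 and 97 without embryo 2, 3 and 4, 912 without pericarp 1, and 173, 673 and 168 without endosperm 2, 3 and 4. For aleurone against the rest 96 genes were higher and 0 lower (edgeR, 4185 at an unadjusted p below 0.05; 3088 called by DESeq2 and 1407 by limma voom), and the count was 40, 12 and 17 without aleurone 1, 2 and 3, 36, 35 and 38 without embryo 2, 3 and 4, 714, 291 and 242 without pericarp 1, 3 and 4, and 41, 43 and 34 without endosperm 2, 3 and 4. In pericarp the SWEET11 call ended without aleurone 3 (edgeR adjusted p = 0.0544) and the SUT1 call without aleurone 1 or 3 or any embryo library (0.0501 to 0.0637), and in aleurone the SUT1 call without aleurone 2 or 3, embryo 3 or endosperm 3 (0.0532 to 0.0801), the SWEET11 call without any aleurone or embryo library or endosperm 3 (0.0651 to 0.134) and the SAPK2 call without any library but the pericarp ones (0.0715 to 0.225).

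Tests against each of the 3 other tissues gave 248 pericarp-depleted genes (2699 by DESeq2 and 588 by limma voom), among them ATG8B, ATG8C, PHR2, RPL11_2 and CDKG-1, each at 0 in all 3 pericarp libraries. In embryo 51 genes were depleted, of which WAXY alone had a symbol, in endosperm gene:BGIOSGA012048 and gene:BGIOSGA019592, and in aleurone 0 genes (120 by DESeq2 and 0 by limma voom). The embryo-enriched genes were gene:BGIOSGA014966 alone with edgeR, 229 genes with DESeq2 and 1396 with limma voom, and 0 genes were enriched in pericarp, aleurone and endosperm with edgeR, where DESeq2 gave 4, 32 and 121 and limma voom 7, 55 and 120. These sets require 3 calls each, so that no single unadjusted p belongs to them. The F test between any tissues called 291 genes.

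Pericarp-depleted genes numbered 0 without aleurone 1 or 3, any embryo library, or endosperm 2 or 4, and also with lane as a covariate and with library totals alone, and they numbered 410, 706, 456 and 493 without aleurone 2, pericarp 1, pericarp 3 and endosperm 3. Embryo-depleted genes numbered 33, 33 and 31 without embryo 2, 3 and 4, and the F test called from 60 (without embryo 3) to 898 (without pericarp 1), with each of the 12 libraries moving its count by more than 1.5 times.

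**Figure D3:**
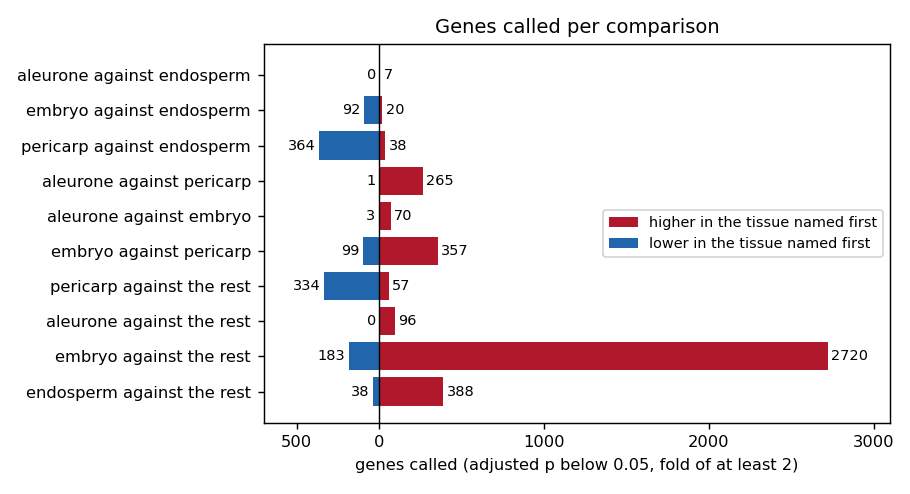
Genes called higher (to the right) and lower (to the left) in each pairwise comparison and in each tissue against the rest (horizontal axis, number of genes at an adjusted p below 0.05 and a fold of at least 2). Embryo against the rest has the most calls, 2720 higher and 183 lower, and aleurone against endosperm the fewest, 7 higher.

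Among the planned lists, that of sugar transport and cleavage stood higher in pericarp and lower in embryo. The members used were all transporters, so the result does not cover sugar cleavage genes. In pericarp SUT1 and SWEET11 were called higher over all genes tested and 4 members did not pass, while 4 were higher and 1 lower when adjusted over the list alone. The list passed camera (adjusted p = 0.000834, and 0.0769 with an estimated correlation), but not without pericarp 1 (adjusted p = 0.0756). In embryo the same 2 genes were lower, over all genes and adjusted over the list alone (camera adjusted p = 0.00244, and 0.0777 with an estimated correlation). In endosperm SWEET14 was higher, both ways, and in aleurone SUT1 and SWEET11, both ways, with camera adjusted p = 0.679 and 0.287. SWEET4, SWEET15 and SUT4 were the other members used, and SWEET4 had 56.1 ± 97.2 CPM in pericarp, all of it in 1 library.

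Of the other planned lists 3 had 1 or 2 members that were matched and used, and 6 had none (seed globulins, both lists of starch synthesis, embryo regulators, phytate and metal storage, and grain filling). OLE18, the only aleurone list member used, was called lower in endosperm. Adjustment over a list of 1 member changes nothing, and at an unadjusted edgeR p below 0.05 OLE18 was higher in aleurone and embryo. Of 16347 genes tested 4185 had such a p in aleurone against the rest and 6183 in embryo. RAB16C, the only member used of the list of abscisic acid and desiccation genes, passed in no tissue either way, at 217 ± 195 CPM in aleurone, 252 ± 132 in embryo, 18.9 ± 6.59 in endosperm and 12.2 ± 20.8 in pericarp (SD, n = 3). Of the pigment genes used, the chalcone isomerase gene CHI had 640 ± 833 CPM in pericarp and 127 ± 61.1 in aleurone, and the chalcone synthase gene CHS1 14.1 ± 24.5 and 0. Embryo held more CHS1 than pericarp, a mean of 21.3 CPM. For CHI and CHS1 the SD in pericarp exceeded the mean. Neither was called in any tissue over all genes, and both were higher in pericarp and 1 in embryo when adjusted over the list alone.

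Among the lists drawn up from the table's symbols, the lipid transfer genes gave the lowest p, in pericarp (camera adjusted p = 1.4e-06, and 0.0769 with an estimated correlation), although none of the 5 was called there over all genes. LTP had 551 ± 114 CPM in pericarp, LTP110-A_1 99.5 ± 105 and LTP2-A_1 34.9 ± 24.7 (SD, n = 3). In embryo LTP was lower and LTP110-A_2 was called higher against the mean of the rest, at 27.2 ± 2.83 CPM, although pericarp held 32.0 ± 54.9 and aleurone and endosperm were at 0. The tested members of the larger sugar list were those of the planned one and CIN2, so its tests largely repeat those above. It passed in pericarp (camera adjusted p = 0.00026, and 0.0769 with an estimated correlation) and in embryo (0.00454, and 0.0829 with an estimated correlation), again with SUT1 and SWEET11. HD-Zip homeobox genes stood lower in endosperm (camera adjusted p = 0.0374, and 0.573 with an estimated correlation) with none of 11 called there, and HOX33 had 268 ± 25.2 CPM in embryo and 25.8 ± 22.9 in endosperm. Oil body, late embryogenesis and dehydrin genes stood higher in aleurone (camera adjusted p = 0.0488, and 0.573 with an estimated correlation) with none of 5 called there, led by OLE18 and LEA19. The HD-Zip result ended with library totals alone (camera adjusted p = 0.0548), without both shallowest libraries (0.135), and without aleurone 1 or 3, embryo 3, pericarp 1 or 4, or any endosperm library (camera adjusted p 0.0514 to 0.117), and the oil body result without aleurone 1 or 3, pericarp 1 or 4, or endosperm 3 or 4 (0.0551 to 0.118). The oil body result also ended with library totals alone (camera adjusted p = 0.0548), lane as a covariate (0.0547), at least 5 CPM in 3 libraries (0.0533) and without both shallowest libraries (0.0693). With an estimated correlation 0 of the 68 tests passed, against 7 with the preset one, among them both overlapping sugar lists in pericarp and in embryo.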

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

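Lane as a covariate, limma voom, the 2 other quasi-likelihood settings, TMM without the most abundant genes, thinning, and leaving out the shallowest libraries were chosen only after results were seen. None of the 116 calls of genes with a symbol reversed its direction under any of 28 settings. All 116 held without a fold minimum, a setting that cannot end a call. With a fold minimum of 4, 115 held, and 113 with TMM without the 10 most abundant genes. From 100 to 109 held with limma voom, DESeq2 (of 109 with an adjusted p), DESeq2 size factors, no filter, other quasi-likelihood settings or thinning. All 111 that could be tested held with at least 5 CPM in 3 libraries. Library totals alone kept 93, leaving out the shallowest libraries 83, fits of 2 tissues 19 of 33, lane as a covariate 69, and single libraries left out from 19 (aleurone 3) to 100 (pericarp 1). Every WAXY call ended with limma voom (adjusted p from 0.938 to 0.979). Against TMM, library totals moved the median log2 fold change over all genes by up to 1.67 (pericarp against endosperm), and DESeq2 size factors by -0.51 (embryo against pericarp). Counts below moved by more than 1.5 times, and except where fewer libraries or genes entered the fit, the cause was not tested. The floor of 3 counts over a tissue's libraries was highest in pericarp (0.137 CPM) and nearly as high in endosperm (0.122). It therefore does not show depth to be the main limit of the pericarp. Alternatives with storage protein genes were not run, pseudocounts had no use in count tests, genes differing between any tissues has no fold minimum, and DESeq2, limma voom, the other quasi-likelihood settings and fits of 2 tissues were not used for list tests.

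The numbers of calls in the report were 7 for aleurone against endosperm, 112 for embryo against endosperm, 402 for pericarp against endosperm, 266 for aleurone against pericarp, 73 for aleurone against embryo, 456 for embryo against pericarp, 0 for pericarp-enriched genes, 248 for pericarp-depleted genes, 0 for aleurone-enriched genes, 0 for aleurone-depleted genes, 1 for embryo-enriched genes, 51 for embryo-depleted genes, 0 for endosperm-enriched genes, 2 for endosperm-depleted genes, 391 for pericarp against the rest, 96 for aleurone against the rest, 2903 for embryo against the rest, 426 for endosperm against the rest, 291 for genes differing between any tissues and 7 for gene lists, the last being list tests passed. DESeq2 size factors in the edgeR fit gave 12 for aleurone against endosperm, 2 for endosperm-enriched genes and 4 for endosperm-depleted genes. Library totals alone gave 20 for aleurone against endosperm, 128 for pericarp against endosperm, 0 for aleurone against pericarp, 286 for embryo against pericarp, 0 for pericarp-depleted genes, 1 for endosperm-enriched genes, 14 for endosperm-depleted genes, 251 for pericarp against the rest, 50 for aleurone against the rest, 144 for endosperm against the rest and 142 for genes differing between any tissues. The DESeq2 test gave 2359 for aleurone against endosperm, 3095 for embryo against endosperm, 4932 for pericarp against endosperm, 4436 for aleurone against pericarp, 1357 for aleurone against embryo, 5259 for embryo against pericarp, 4 for pericarp-enriched genes, 2699 for pericarp-depleted genes, 32 for aleurone-enriched genes, 120 for aleurone-depleted genes, 229 for embryo-enriched genes, 296 for embryo-depleted genes, 121 for endosperm-enriched genes, 782 for endosperm-depleted genes, 5383 for pericarp against the rest, 3088 for aleurone against the rest, 4633 for embryo against the rest, 4058 for endosperm against the rest and 2376 for genes differing between any tissues. With no filter beyond 1 count there were 31 for aleurone against endosperm, 107 for aleurone against pericarp, 102 for pericarp-depleted genes, 1 for aleurone-enriched genes, 8 for endosperm-enriched genes and 8 for endosperm-depleted genes. With at least 5 CPM in at least 3 libraries there were 12 for aleurone against endosperm, 1 for endosperm-enriched genes, 4 for endosperm-depleted genes and 741 for genes differing between any tissues. Fits of only the 2 tissues compared gave 82 for aleurone against endosperm, 4266 for embryo against endosperm, 0 for pericarp against endosperm, 0 for aleurone against pericarp, 388 for aleurone against embryo and 5638 for embryo against pericarp. Lane as a covariate gave 4 for aleurone against endosperm, 182 for pericarp against endosperm, 0 for aleurone against pericarp, 186 for embryo against pericarp, 0 for pericarp-depleted genes, 0 for embryo-enriched genes, 1 for endosperm-depleted genes, 146 for pericarp against the rest, 46 for aleurone against the rest, 1863 for embryo against the rest, 264 for endosperm against the rest and 138 for genes differing between any tissues. Limma voom gave 719 for aleurone against endosperm, 4667 for embryo against endosperm, 1688 for pericarp against endosperm, 1681 for aleurone against pericarp, 2251 for aleurone against embryo, 7222 for embryo against pericarp, 7 for pericarp-enriched genes, 588 for pericarp-depleted genes, 55 for aleurone-enriched genes, 1396 for embryo-enriched genes, 120 for endosperm-enriched genes, 44 for endosperm-depleted genes, 4918 for pericarp against the rest, 1407 for aleurone against the rest, 6688 for embryo against the rest, 2663 for endosperm against the rest and 7183 for genes differing between any tissues. Quasi-likelihood without the legacy setting gave 70 for aleurone against endosperm, 441 for embryo against endosperm, 707 for pericarp against endosperm, 151 for aleurone against pericarp, 151 for aleurone against embryo, 956 for embryo against pericarp, 134 for pericarp-depleted genes, 1 for aleurone-enriched genes, 8 for embryo-enriched genes, 86 for embryo-depleted genes, 22 for endosperm-enriched genes, 18 for endosperm-depleted genes, 252 for aleurone against the rest, 931 for endosperm against the rest and 1527 for genes differing between any tissues. The robust prior gave 17 for aleurone against endosperm, 100 for aleurone against pericarp, 95 for pericarp-depleted genes, 2 for embryo-enriched genes, 4 for endosperm-enriched genes and 5 for endosperm-depleted genes. TMM without the 10 most abundant genes of each library gave 1 for aleurone-enriched genes. Leaving out the shallowest aleurone and endosperm libraries together gave 0 for aleurone against endosperm, 55 for embryo against endosperm, 1377 for pericarp against endosperm, 1670 for aleurone against pericarp, 24 for aleurone against embryo, 2422 for embryo against pericarp, 1161 for pericarp-depleted genes, 0 for embryo-enriched genes, 23 for embryo-depleted genes, 0 for endosperm-depleted genes, 1314 for pericarp against the rest, 1 for aleurone against the rest, 139 for endosperm against the rest and 35 for genes differing between any tissues. Thinning every library to the smallest total gave 3 for aleurone against endosperm, 1022 for embryo against pericarp, 0 for embryo-enriched genes and 1 for endosperm-depleted genes. With 1 library left out at a time, the counts ranged from 33 to 108 for aleurone against embryo, from 0 to 66 for aleurone against endosperm, from 0 to 860 for aleurone against pericarp, from 12 to 714 for aleurone against the rest, from 0 to 0 for aleurone-depleted genes, from 0 to 3 for aleurone-enriched genes, from 49 to 253 for embryo against endosperm. They ranged from 108 to 925 for embryo against pericarp, from 78 to 2873 for embryo against the rest, from 31 to 72 for embryo-depleted genes, from 0 to 8 for embryo-enriched genes, from 112 to 984 for endosperm against the rest, from 0 to 22 for endosperm-depleted genes, from 0 to 19 for endosperm-enriched genes. They ranged from 4 to 8 for gene lists, from 60 to 898 for genes differing between any tissues, from 113 to 1015 for pericarp against endosperm, from 95 to 912 for pericarp against the rest, from 0 to 706 for pericarp-depleted genes, from 0 to 1 for pericarp-enriched genes.

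The replicate numbers did not pair the libraries: over 13 pairs with the same number, deviations from the tissue means correlated at -0.0382 to 0.0263, none over 0.1, and 2 of 12 libraries correlated best with their own number. Serial numbers in the headers run in another order, with aleurone 2, endosperm 3 and embryo 3 in sequence. These had the fewest genes of their tissues (8158, 6780 and 14326). Pairs by serial number were not tested as a set. Pericarp 1, aleurone 1, endosperm 2 and embryo 2 also run in sequence, as do pericarp 3, aleurone 3, endosperm 4 and embryo 4. The highest values of any pair lay within such runs. They were 0.0429 (aleurone 1 with embryo 2), 0.0419 (aleurone 1 with endosperm 2) and 0.0418 (aleurone 2 with endosperm 3). Negative values in the runs were -0.0382 (aleurone 1 with pericarp 1), -0.00232 (aleurone 3 with embryo 4) and -0.00113 (pericarp 3 with endosperm 4). The rest were positive. A shared preparation therefore stays open, and the block may not hold it. With the replicate block, in counts of calls, there were 128 for aleurone against endosperm, 370 for embryo against endosperm, 66 for aleurone against pericarp, 159 for aleurone against embryo, 46 for pericarp-depleted genes, 1 for aleurone-enriched genes, 4 for embryo-enriched genes, 79 for embryo-depleted genes, 42 for endosperm-enriched genes, 17 for endosperm-depleted genes, 190 for pericarp against the rest, 392 for embryo against the rest and 580 for genes differing between any tissues. Of the 116 calls of genes with a symbol, 48 held with the replicate block and 68 did not pass, and the oil body list in aleurone had a camera adjusted p of 0.14. With camera's estimated correlation, 0 list tests passed.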

Other observations

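The test of reads assigned to the wrong library of a lane was chosen only after the WAXY counts were seen, and the carry-over shares of single genes only after the lowest share was tested. The other tests in this part were written down before their results. Of all 16347 genes tested, 2720 were called higher and 183 lower in embryo against the rest, so a few called members do not mark a group there. Several gene groups held 1 to 3 called members against the rest, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In embryo these were TROL and LTD of 5 photosynthesis genes, AOC and TIFY6A of 6 jasmonate genes, IAA13, ARF10 and lower DAO of 10 auxin genes, RR23 of 7 cytokinin genes, MYBS2 of 4 gibberellin genes, CSLC10 of 7 cell wall genes, SAPK2 of 3 abscisic acid genes, APX1 of 6 metallothionein and antioxidant genes, RAB16D of 5 oil body and dehydrin genes, RPL11_2 of 6 ribosomal protein genes, ATG8C of 4 autophagy genes and PHR2 of 15 phosphate and inositol phosphate genes. Of these RAB16D, ATG8C and PHR2 were at 0 in pericarp, and another tissue held more than embryo: RAB16D had 33.5 ± 20.3 CPM in embryo and 41.1 ± 38.0 in aleurone, ATG8C 44.4 ± 15.5 and 114 ± 51.8 in endosperm, and PHR2 29.6 ± 13.7 and 81.4 ± 16.6 in endosperm (SD, n = 3). In endosperm PHR2, RPL11_2 and CESA5 of those lists were higher against the rest, RPL11_2 at 66.4 ± 25.7 CPM with 96.5 ± 20.5 in embryo, and in pericarp all 3 were lower. None of the lists among these with 5 or more tested members passed camera in any tissue, apart from the oil body list in aleurone. The lowest adjusted p of the others were 0.119 for photosynthesis genes in aleurone, 0.198 for phosphate genes in embryo, and 0.207 for antioxidant genes in pericarp and for cell wall genes in endosperm.

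Some genes had counts in every library and were called in no comparison. ATG8A had 90.2 ± 37.6 CPM in pericarp, 74.3 ± 16.6 in aleurone, 69.5 ± 16.1 in embryo and 73.4 ± 16.3 in endosperm (SD, n = 3), and the thioredoxin gene TRXH 128 ± 31.4, 182 ± 71.8, 69.3 ± 16.5 and 154 ± 11.4. The cellulose synthase gene CESA1 had 225 ± 167, 189 ± 60.1, 189 ± 43.9 and 365 ± 61.8. The metallothionein gene MT2C had 527 ± 106 CPM in embryo and 72.0 ± 18.7 in aleurone. By edgeR's test no member passed against the rest in the lists of flavonoid synthesis (2 tested), ethylene (4), fermentation (3), MADS-box (2), WRKY (1), magnesium transporter (4), calmodulin (5) and actin (2) genes, and calmodulins did not pass camera (lowest adjusted p = 0.789).

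The pericarp libraries counted few genes. Thinned to 2879282 counts, 9 of 9 libraries of the other tissues still held more genes than the highest pericarp library, and also 9 of 9 after the 10 most abundant genes were left out, which argues against depth and against a few dominant genes as the whole cause. Of 3361 genes seen in all 9 other libraries, 318 were missing from all 3 pericarp libraries, 1.15 times the 275.8 that independent losses give, and 1859 from 1 or 2. This is in line with random loss of transcripts in each pericarp library, a candidate explanation for many of the absences, including some of the 248 pericarp-depleted genes, while a smaller set of transcripts in the pericarp itself would raise the ratio and stays open for the small excess and for genes not seen in all 9 other libraries. The same ratio was 11.3 in endosperm (13 of 1423 genes, 1.15 expected) and 268 in embryo (7 of 1228, 0.0261 expected), and in aleurone 0 of 1270 genes were missing from all 3 libraries (0.00174 expected).

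WAXY had 2101 ± 874 CPM in aleurone and 1212 ± 1010 in pericarp, against 7.96 ± 10.4 in embryo (SD, n = 3). Misassigned reads within a lane would reach the embryo libraries as well, and the highest embryo library had 5.82% of the lowest aleurone or pericarp library in lane 5 and 0.296% in lane 6, which argues against that source. Endosperm RNA in these samples may be the source: WAXY would need a share of 3.59% in aleurone and 2.07% in pericarp, and 0% of 50 abundant endosperm genes lay far below the level (under 0.25 of it) which that share needs in aleurone and 0% in pericarp, against 22% in embryo at its own share. The bar was a low one, since 45 of the 50 lay at or above that share in aleurone and 43 in pericarp (medians of 11.6% and 6.41% of the endosperm level), so that carry-over at the WAXY share does not account for their whole level. Expression of WAXY in aleurone and pericarp stays open too.

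SUT1, SWEET11, LTP and OLE18 were abundant in both pericarp and aleurone, which adjoin in the grain. As aleurone RNA in the pericarp samples, SUT1 would need a share of 36.8%, the lowest of the 4, at which 0% of 50 aleurone genes lay far below the needed level in pericarp. OLE18, LTP and SWEET11 would need 61.4%, 69.1% and 124%, at which (SWEET11 at 100%) 6%, 8% and 22% of them did. As pericarp RNA in the aleurone samples, SWEET11 would need 80.5%, at which 0% of 50 pericarp genes lay far below, while LTP, OLE18 and SUT1 would need 145%, 163% and 272%, more than carry-over of RNA can give. Since the log2 fold changes between the 2 tissues were within about 1 SE of 0, these shares exclude neither source, and carry-over in either direction and expression in both tissues cannot be told apart.

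Other groupings of the 12 libraries into 4 sets of 3 were counted, 100 in all with the real one. A share below 0.05 of the groupings gave as large a count for the F test (1 of 100 as large, 291 against at most 263 elsewhere), pericarp against the rest (2, 391 against 1382), embryo against the rest (1, 2903 against 413), endosperm against the rest (1, 426 against 199), pericarp-depleted genes (1, 248 against 77) and embryo-depleted genes (3, 51 against 87). The groupings shuffled all 4 tissues at once. A low share therefore argues against chance for the tissue labels as a whole and cannot say which tissue carries a count. Pericarp-depleted genes numbered 0 with lane as a covariate, with library totals alone and without any single embryo library. For embryo-enriched genes 2 of 100 groupings gave as many (1 against 25), a share that rests on a count of 1 gene, which was 0 without any single aleurone, embryo or endosperm library. Chance cannot be excluded for aleurone against the rest (10, 96 against 1661), endosperm-depleted genes (22, 2 against 59) or list tests passed (7, 7 against 12). The groupings with 1382 and 1661 calls put the 3 embryo libraries together as 1 of their sets, so that the embryo stood out most in these edgeR fits. That ranking depended on the fit. DESeq2 called 5383 genes for pericarp against the rest and 4633 for embryo. Without aleurone 3 edgeR called 78 for embryo, 104 for pericarp and 119 for endosperm. For pairs, 10 splits of 6 libraries are too few for a share below 0.05. Real and highest other counts in fits of those 6 were 82 and 0 for aleurone against endosperm (1 split as large), 4266 and 0 for embryo against endosperm (1), 388 and 0 for aleurone against embryo (1) and 5638 and 8 for embryo against pericarp (1). They were 0 and 0 for pericarp against endosperm and for aleurone against pericarp, where all 10 splits tied.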
